A study of Mus musculus with 27 samples.

How the data were processed

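Gene counts of 27 mouse libraries were used, 15 from dorsal root ganglia and 12 from picked retinal ganglion cells, with 3 libraries in each of 9 groups. Both deposited tables hold raw counts per gene symbol, with 1 column per library and the same symbols in the same order. For both, reads were trimmed with Trim Galore and aligned with STAR to GRCm38 (mm10), per the submitters' processing notes; the versions are not given in the sources used here. The ganglion counts were made with featureCounts 2.0.1 on the Ensembl release 101 annotation, per the file headers, from paired primary alignments with a mapping quality of 10 or more, without regard to strand and over all exons of a gene. That command names 20 alignment files, of which 15 have a column. The gene lengths (unit bp) in the deposited ganglion table were not used. The program that counted the retinal reads and its annotation are not given in the sources used here. In the retinal table the last line has no gene name and equals the column sum in 12 of 12 libraries, 50% of the file total; it was left out of library sizes and tests. Because ganglion reads were counted without strand, counts of overlapping genes and of antisense transcripts are uncertain.

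Groups were taken from the labels. Per the labels, ganglia are L4-L5 ganglia and the series text speaks of nerve samples, and the control is called intact in titles and sham surgery in the treatment field; it is called sham here. Whether replicates are separate animals, and how many cells a retinal library holds, is not given in the sources used here. No pair of libraries of a table held the same counts. The floor of detection was taken as 3 counts per library, given as CPM under Results. A single ribosomal sequence entry, CT010467.1, took 1.98% to 7.51% of ganglion and 22.1% to 35.7% of retinal counts.

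Each experiment was fitted separately with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group (minimum count 10, minimum total 15), a quasi-likelihood fit with robust dispersions over all groups, and Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison (18517 in ganglia, 13487 in retinal cells). The biological coefficient of variation was 0.262 and 1.27. Comparisons in ganglia were injury in each genotype, genotype in sham and in injured mice, the difference of both injury effects (interaction), and RU521 in injured wild type. In retinal cells they were IFNγ in each genotype, genotype with PBS and with IFNγ, the interaction, and the knockout with IFNγ against wild type with PBS. Levels are TMM-scaled CPM. Where a group had 0 counts the fold is a bound from 3 counts per library, and where it had 1 to 3 counts in all the ratio has an exact 95% counting interval. Fitted log2 values use edgeR's prior count of 0.125.

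26 gene lists were written before the data were examined: regeneration-associated, IFNγ response, type I interferon-stimulated, MHC class I and class II presentation, cGAS-STING, JAK-STAT, chemokines and cytokines, integrated stress response, immediate early, proliferation, neuronal apoptosis, and marker lists of macrophages and microglia, T and NK cells, neutrophils, endothelium and fibroblasts, red blood cells, sensory neurons, satellite glia, myelinating Schwann cells, retinal ganglion cells, rods, cones, Müller glia and astrocytes, amacrine and horizontal cells, and bipolar cells. Egr2 is in 2 lists, as are Nefh, Isl1 and Tubb3, and 5 genes are shared by the Müller glia and satellite glia lists. Lists with 5 or more measured genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with the correlation estimated for each list. Counts "over the list alone" adjust the p-values of a list's genes among themselves.

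Named genes follow a rule fixed before the data were examined: Ptpn2, and Cgas for RU521; the 8 largest increases and decreases per comparison (4 for interactions) that passed, reached a mean of 5 CPM and did not overlap between libraries (not asked for interactions), without predicted, pseudogene and mitochondrial symbols, or the 3 smallest p-values where none passed; and per list up to 4 called members with the smallest p, or the 2 with the highest level where none was called. Some genes that this rule picks are not reported here.

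Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no low count filter, DESeq2 1.42.0, limma-voom with sample quality weights, a fit of only the groups compared, the replicate number as an additive factor, and leaving out each library in turn. Added after the data were examined were the number of detected genes as a covariate and the omission of both ganglion libraries that stood apart from their group. The tests were tested on simulated data with the dispersions of these libraries: edgeR found 39.4%, 72.5% and 96.5% of genes changed by a log2 of 1, 2 and 4 for injury in wild type (7.09% of calls false), and 14.5%, 66.7% and 78% for the ganglion interaction (3.92% false). For the retinal comparison of both treatments it found 0%, 1.52% and 20.8% (0% false). Camera found the raised list in each and called 0, 0 and 2 of 50 unchanged lists at an unadjusted p below 0.05. Transcript-level and exon-level analysis was not done, since the files hold gene counts.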

Results

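Polyadenylated RNA of mouse tissue was sequenced in 27 libraries of 2 experiments, each with 3 replicates per group. In the ganglion experiment, 15 bulk libraries came from lumbar dorsal root ganglia, which hold the cell bodies of the sensory neurons of the sciatic nerve. Its groups were wild type after sham surgery or sciatic nerve injury, Ptpn2 knockout after sham surgery or injury, and injured wild type given RU521. RU521 inhibits the DNA sensor cGAS. In the retinal experiment, 12 libraries came from picked retinal ganglion cells, whose axons form the optic nerve, all after its injury. Its groups were wild type and Ptpn2 knockout, each injected with buffer (PBS) or interferon gamma (IFNγ). Per the labels, samples were taken 3 days after injury, and all retinal groups had a viral vector (AAV) 2 weeks before it. Ptpn2 encodes a tyrosine phosphatase that acts on JAK and STAT proteins.

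Ganglion libraries held 14813365 to 22414750 counts and 26235 to 34340 detected genes. In the order of the groups above, the 3 replicates held 22414750, 16427052 and 18110613, then 15982674, 18418172 and 15450792, 16630614, 17260391 and 14813365, 15688295, 15517976 and 15544530, and 16914909, 15562227 and 15925690 counts. Retinal libraries held 13239988 to 17122057 counts and 11508 to 13866 detected genes. Their replicates held 13239988, 17122057 and 13739774 counts in wild type with PBS and 16042074, 15358575 and 16517188 in wild type with IFNγ. The knockout libraries held 14949854, 14516495 and 15214203 with PBS and 14153159, 15557546 and 14356256 with IFNγ. A level below 3 counts, or 0.134 to 0.203 CPM (counts scaled by library size) in ganglia and 0.175 to 0.227 CPM in retinal cells, was taken as under the detection floor. Intervals and floors cover counting error only, and every p-value measures only the spread between these libraries. Levels are given as TMM-scaled CPM, mean ± SD with n = 3, and fold changes as log2 values ± SE.

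Ptpn2, on chromosome 18 of GRCm38 (67665511 to 67724595, minus strand), was detected in every ganglion library. Its level was 11.6, 19.3 and 12.9 CPM in wild-type sham, 15.9, 19.8 and 17.5 CPM in wild-type injured, and 15.4, 18.1 and 14.0 CPM with RU521. The knockout libraries held 15.8, 12.1 and 10.5 CPM after sham surgery and 24.1, 26.5 and 18.5 CPM after injury. Between genotypes, Ptpn2 did not pass the test in sham (-0.19 ± 0.22) or in injured ganglia (0.38 ± 0.22), whereas it rose with injury in the knockout by 0.84 ± 0.22. In retinal cells it stood at 10.5, 7.26 and 3.39 CPM (wild type, PBS), 0, 9.88 and 14.1 CPM (wild type, IFNγ), 10.1, 8.06 and 7.71 CPM (knockout, PBS) and 15.5, 0 and 23.9 CPM (knockout, IFNγ). Gene counts sum all exons, so a transcript that lacks only the deleted part is still counted, as are intact transcripts of any cells without Cre (the driver used in ganglia is not given in the sources used here). The gene count therefore neither checks nor contradicts the genotype labels, and all directions below rest on the labels.

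Sciatic nerve injury in wild-type mice raised a set of neuronal injury genes in the ganglia and lowered genes of mature sensory neurons. Sprr1a, a small proline-rich protein of injured neurons (chromosome 3, 92483952 to 92485895), stood at 562 ± 206 CPM after injury against 1.93 ± 0.595 CPM after sham surgery, a log2 fold change of 8.20 ± 0.44. Atf3, a stress-induced transcription factor, rose from 7.89 ± 1.49 to 292 ± 103 CPM (5.21 ± 0.41), and the neuropeptide gene Gal rose from 18.4 ± 4.19 to 396 ± 118 CPM (4.43 ± 0.32). Nefh, the heavy neurofilament of large axons, fell from 643 ± 49.9 to 190.5 ± 7.06 CPM (-1.76 ± 0.29). The comparison asks what the ganglion transcribes in response to axon injury, the background for the effect of Ptpn2 on regeneration.

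Among the other largest increases were Npy (5.66 ± 0.47), a neuropeptide of injured large neurons, Gpr151 (5.53 ± 0.42), an orphan receptor, and Cckbr (6.40 ± 0.61), a cholecystokinin receptor. Crh (5.40 ± 0.68), a stress hormone, Lipn (6.31 ± 0.62), a lipase, and Slc6a4 (4.96 ± 0.80), the serotonin transporter, also rose. The largest decreases were in Ajm1 (-2.25 ± 0.40), Marchf9 (-2.24 ± 0.43), the kinase inhibitor Camk2n2 (-2.23 ± 0.49), the potassium channel Kcnc1 (-2.23 ± 0.33) and Tpbgl (-2.13 ± 0.44). Pvalb, a calcium buffer of proprioceptive neurons, fell by 2.11 ± 0.47 from a sham level of 453 ± 442 CPM that 1 library carried (963 CPM in wild-type sham replicate 2). The somatostatin receptor Sstr2 (-2.11 ± 0.38) and Frrs1l (-2.06 ± 0.32), a partner of AMPA receptors, fell too.

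Of 28 measured regeneration-associated genes, 22 rose and 0 fell after injury in wild type, also 22 when adjusted over the list alone, with a median of 1.99 (camera adjusted p = 1.14e-35, and adjusted p = 0.0129 with an estimated correlation). Of 23 genes of sensory neuron identity and channels, 15 fell, 17 when adjusted over the list alone, with a median of -0.98 (camera adjusted p = 3.56e-11; adjusted p = 0.122 with an estimated correlation). They included the peptide genes Calca (1020 ± 212 against 1882 ± 207 CPM; -0.88 ± 0.15) and Tac1 (-1.48 ± 0.26) and the transcription factor Isl1 (-0.89 ± 0.18). Of 11 immediate early genes 6 rose, 7 over the list alone, such as Btg2 (1.60 ± 0.29), Fos (1.15 ± 0.27) and Junb (0.77 ± 0.17), with adjusted p = 0.12 with an estimated correlation. Fosb, also called, had 41 counts against 3, a ratio of 15.8 (counting interval 5.03 to 79.6). In the integrated stress response 1 of 14 rose, also 1 over the list alone, Chac1 (1.13 ± 0.33), and the list did not pass (camera adjusted p = 0.252).

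Markers of other cell types moved with injury in wild type as well. Of 18 macrophage and microglia markers, 16 rose, 17 when adjusted over the list alone, with a median of 1.73, among them the lysozyme Lyz2 (2049 ± 173 against 422 ± 272 CPM), the mannose receptor Mrc1 (2.03 ± 0.33), Adgre1 (2.32 ± 0.37) and Cd68 (1.92 ± 0.37). All 7 neutrophil markers rose, also over the list alone (median 2.33), with the chemokine receptor Cxcr2 at 2.92 ± 0.41 and the protease Mmp9 at 2.58 ± 0.37, together with Ly6g (2.75 ± 0.44) and Retnlg (2.33 ± 0.40). All 5 red blood cell genes rose, also over the list alone (median 1.82), and the globin Hbb-bs stood at 5643 ± 38.7 against 1637 ± 1639 CPM. Of 12 proliferation genes 11 rose, 12 over the list alone (median 1.74), such as the cyclins Ccnb1 (2.80 ± 0.51) and Ccna2 (2.24 ± 0.42), Rrm2 (1.97 ± 0.40) and Birc5 (1.79 ± 0.37). Of 10 myelinating Schwann cell markers 5 rose, 8 over the list alone (median 0.65), including myelin basic protein Mbp (11460 ± 94.5 against 5069 ± 2614 CPM), Drp2 (1.24 ± 0.22), Pmp22 (0.67 ± 0.15) and Mal (0.61 ± 0.14). Sham levels of such markers were lowest in replicates 1 and 3, with the red blood cell gene Alas2 at 28.1, 99.3 and 35.4 CPM in replicates 1, 2 and 3. With an estimated correlation these 5 lists gave camera adjusted p = 0.12, 0.0964, 0.122, 0.122 and 0.122 in this order. Of 11 endothelial and fibroblast markers 4 rose, also 4 over the list alone, such as the proteoglycans Lum (1.05 ± 0.17) and Dcn (0.77 ± 0.21) (adjusted p = 0.358 with an estimated correlation). Of 10 T and NK cell markers 1 rose and 0 over the list alone, the granule protein Nkg7 (1.74 ± 0.55) (adjusted p = 0.433 with an estimated correlation). Of 10 satellite glia markers 4 rose and 1 fell, the same over the list alone, with the filament Gfap at 2.68 ± 0.51 and Aldoc at -0.70 ± 0.19, and the list did not pass (camera adjusted p = 0.219).

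Few interferon genes passed for injury in wild type. Of 28 IFNγ response genes 4 rose, also 4 over the list alone, namely the GTPases Gbp9 (1.30 ± 0.22) and Igtp (0.49 ± 0.14), the complement inhibitor Serping1 (0.53 ± 0.16) and Irf9 (0.65 ± 0.20) (median 0.40, adjusted p = 0.452 with an estimated correlation). Of 28 type I interferon-stimulated genes 2 rose, 1 over the list alone, Rsad2 (1.59 ± 0.38) and Oas3 (1.95 ± 0.57) (median 0.33, adjusted p = 0.611 with an estimated correlation). None of 14 genes of MHC class I presentation passed, also 0 over the list alone (camera adjusted p = 0.164), and B2m, the light chain of class I molecules, stood at 757 ± 14.4 against 506 ± 127 CPM. Of 7 class II genes 1 rose, 3 over the list alone, H2-DMa (0.67 ± 0.17) (adjusted p = 0.433 with an estimated correlation). Of 9 genes of the cGAS-STING pathway 5 rose, also 5 over the list alone, including Sting1 (1.37 ± 0.20), the adaptor of cGAS, Ikbke (1.79 ± 0.42), Samhd1 (0.97 ± 0.24) and Cgas itself (2.15 ± 0.525 against 0.623 ± 0.135 CPM) (adjusted p = 0.0772 with an estimated correlation). Of 19 JAK-STAT components 4 rose, 5 over the list alone, among them the phosphatases Ptpn6 (1.80 ± 0.41) and Ptpn1 (0.67 ± 0.15) (adjusted p = 0.292 with an estimated correlation). Of 18 chemokines and cytokines 7 rose, 8 over the list alone, such as Csf1 (2.37 ± 0.32), Osm (4.65 ± 0.74), Il1b (2.61 ± 0.66) and Ccl12 (1.59 ± 0.30) (adjusted p = 0.167 with an estimated correlation).

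edgeR's quasi-likelihood test called 3070 of 18517 genes in this comparison, 1593 higher and 1477 lower. Wild-type sham replicates 1 and 3 had 26235 and 26802 detected genes against 34115 in replicate 2, and 4.87% and 6.52% mitochondrial counts against 15.2%. Injured wild type had 13.2% to 15.7%, so this sign of library quality differs along with injury. Without wild-type sham replicate 1, 2 or 3 the count was 1615, 6513 or 1240, and without wild-type injured replicate 2 or 3 it was 1307 or 1394. With the number of detected genes as a covariate 847 genes were called.

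**Figure D1:**
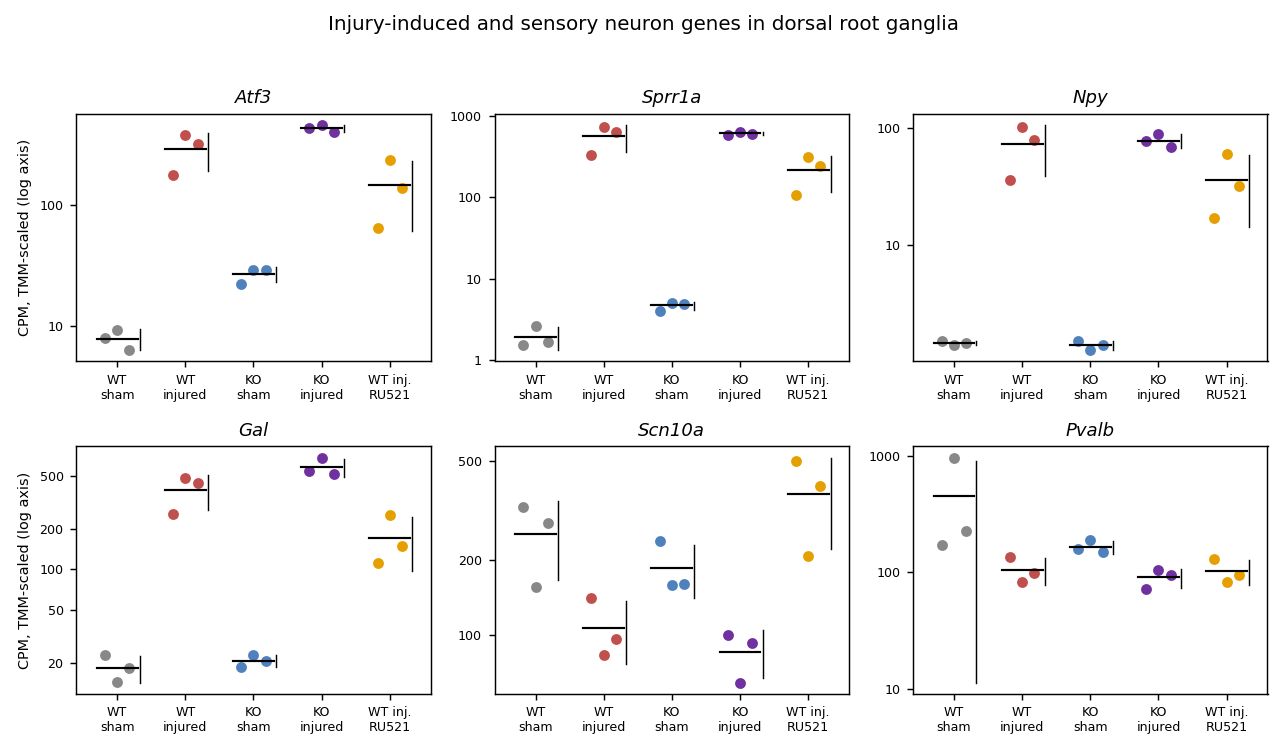
Levels of 4 injury-induced and 2 sensory neuron genes in ganglia (y axis, TMM-scaled CPM, log scale) for the 5 groups; points are libraries, lines means and bars SD (n = 3). Gal stood at 396 CPM after injury in wild type and 587 CPM in the knockout, against 18.4 and 20.7 CPM after sham surgery.

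Injury in Ptpn2 knockout mice raised the injury genes too, and with them the interferon genes. Sprr1a rose from 4.69 ± 0.544 to 605 ± 30.8 CPM (7.01 ± 0.42) and Gal from 20.7 ± 2.08 to 587 ± 89.2 CPM (4.83 ± 0.32). Gbp2, an interferon-induced GTPase (chromosome 3, 142620602 to 142638008), rose from 34.1 ± 6.6 to 714 ± 127 CPM (4.39 ± 0.24), and Cxcl9, a chemokine induced by IFNγ, from 1.51 ± 0.222 to 128 ± 106 CPM (6.40 ± 0.62). Ucp1, the uncoupling protein of brown fat, fell from 65.8 ± 20.1 to 5.81 ± 3.81 CPM (-3.50 ± 0.49). The comparison asks how knockout ganglia respond to axon injury.

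Other large increases in the knockout were in Lipn (6.43 ± 0.63), Crh (6.04 ± 0.69), Npy (78.5 ± 10.2 against 1.38 ± 0.12 CPM; 5.82 ± 0.48), the acute phase gene Saa3 (6.11 ± 0.28) and Ly6i (6.13 ± 0.86). Cplx3, a complexin of synaptic release, had 656 counts against 3, a ratio of 227 (counting interval 77.5 to 1105). Besides Ucp1, the largest decreases were in Cox8b (-4.45 ± 0.98), Pck1 (-3.92 ± 0.61), Cidea (-3.22 ± 0.46), Ces1d (-2.94 ± 0.62), Fabp4 (17.2 ± 12.5 against 107 ± 26.8 CPM; -2.64 ± 0.72) and Elovl3 (-2.50 ± 0.68). Zfp663 fell as well (-3.39 ± 0.72). The fall of Ucp1 and Pck1 starts from sham knockout levels (65.8 and 17.9 CPM) far above those of sham wild type (0.642 and 0.697 CPM).

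Of 28 IFNγ response genes 25 rose with injury in the knockout, 27 when adjusted over the list alone, with a median of 3.06 (camera adjusted p = 3.38e-102; adjusted p = 0.000349 with an estimated correlation). They included the GTPases Igtp (3.24 ± 0.15), Iigp1 (3.81 ± 0.23) and Irgm1 (3.35 ± 0.21). All 28 type I interferon-stimulated genes rose, also over the list alone (median 2.69, adjusted p = 0.0165 with an estimated correlation), with Ifit3 at 706 ± 385 against 61.8 ± 3.94 CPM, the nucleic acid sensor Zbp1 at 4.08 ± 0.43, Rtp4 at 2.64 ± 0.24 and Oasl2 at 2.20 ± 0.24. Of 14 class I genes 13 rose, 14 over the list alone (median 1.71, adjusted p = 0.00632 with an estimated correlation). Examples were the peptide transporter Tap1 (117 ± 32.5 against 18.2 ± 0.771 CPM), the proteasome subunit Psmb8 (2.76 ± 0.28), Psme2 (1.53 ± 0.15) and Tapbp (1.43 ± 0.15). Of 18 chemokines and cytokines 12 rose, 13 over the list alone (median 2.44, adjusted p = 0.0374 with an estimated correlation), with the monocyte attractants Ccl2 (3.23 ± 0.33), Ccl7 (3.53 ± 0.38), Ccl8 (3.84 ± 0.56) and Ccl12 (2.19 ± 0.29). Of 9 cGAS-STING genes 4 rose, also 4 over the list alone: Sting1 (2.27 ± 0.20), Samhd1 (2.17 ± 0.25), Ikbke (2.26 ± 0.42) and Cgas (1.88 ± 0.47) (median 0.33, adjusted p = 0.0142 with an estimated correlation). Of 7 class II genes 2 rose, 4 over the list alone, H2-DMa (1.26 ± 0.17) and H2-DMb1 (1.10 ± 0.27) (adjusted p = 0.224 with an estimated correlation). Of 19 JAK-STAT components 6 rose, 9 over the list alone, such as Ptpn1 (1.09 ± 0.15) and Ptpn6 (1.82 ± 0.41) (adjusted p = 0.0651 with an estimated correlation). Reads of the guanylate-binding protein, H2, Ifit3 and Tgtp families are hard to tell apart between paralogs, so single members of them are less certain than their lists.

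Of 28 regeneration-associated genes 23 rose in the knockout, 25 over the list alone (median 1.86; camera adjusted p = 8.48e-60; adjusted p = 0.000523 with an estimated correlation). Among them was the neuropeptide Nts (175 ± 16.4 against 11.9 ± 2.72 CPM). Of 23 sensory neuron genes 10 fell, 16 over the list alone (median -0.77, adjusted p = 0.17 with an estimated correlation). Examples were the cold channel Trpm8 (-1.54 ± 0.35), Tac1 (-1.09 ± 0.26) and the potassium channels Kcns1 (-1.34 ± 0.33) and Kcna2 (-0.82 ± 0.20). Of 18 macrophage and microglia markers 13 rose, 16 over the list alone (median 1.75, adjusted p = 0.0763 with an estimated correlation). These included the protease Ctss (391 ± 142 against 52.9 ± 10.3 CPM), Cd68 (2.39 ± 0.37), Aif1 (2.68 ± 0.43) and Fcer1g (2.11 ± 0.37). Of 7 neutrophil markers 4 rose, 7 over the list alone, such as Ly6g (1.82 ± 0.43) and Csf3r (1.84 ± 0.47) (adjusted p = 0.195 with an estimated correlation). Of 10 T and NK cell markers 3 rose, 8 over the list alone: Cd4 (2.53 ± 0.53), the granzyme Gzmb (2.98 ± 0.74) and Lck (1.15 ± 0.31) (adjusted p = 0.17 with an estimated correlation). Of 11 immediate early genes 2 rose, also 2 over the list alone, Dusp1 (1.07 ± 0.23) and Junb (0.72 ± 0.16) (adjusted p = 0.253 with an estimated correlation). No proliferation gene passed, also 0 over the list alone, while the list did (median 0.78; camera adjusted p = 0.00188, 0.382 with an estimated correlation).

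In the integrated stress response Chac1 (1.49 ± 0.33), Ddit3 (0.82 ± 0.19) and Trib3 (0.92 ± 0.23) rose and Ddit4 fell (-0.83 ± 0.19), 3 higher and 2 lower over the list alone of 14 (camera adjusted p = 0.0627). Of 10 satellite glia markers Gfap rose (2.65 ± 0.49) and Aldoc (-0.69 ± 0.19) and Apoe (-0.49 ± 0.14) fell, 2 higher and 3 lower over the list alone, and the median (-0.07) and mean (0.12) of the list differ in sign (camera adjusted p = 0.65). Red blood cell genes (median -0.01, mean 0.03) and Schwann cell markers (median -0.01, mean 0.01) did not pass in any gene (camera adjusted p = 0.994 for both), and Mbp stood at 5423 ± 719 against 5475 ± 517 CPM. Of 11 endothelial and fibroblast markers 1 rose, Lum (0.65 ± 0.17), 1 higher and 1 lower over the list alone (camera adjusted p = 0.456).

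edgeR's test called 2021 of 18517 genes for injury in the knockout, 1174 higher and 847 lower. The count was 869, 1388 or 1131 without knockout sham replicate 1, 2 or 3, and 1092, 1039 or 1257 without the corresponding knockout injured replicate; 3114 genes passed with the number of detected genes as a covariate. The genes called in both genotypes in the same direction were 605 higher and 503 lower, 5.99 and 7.45 times as many as in independent lists. Among genes called in both, 4 rose in wild type and fell in the knockout and 1 did the reverse. Across all tested genes the fold changes of both genotypes correlated with a Pearson coefficient of 0.543 and a Spearman coefficient of 0.558.

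In sham-operated mice, where the comparison asks what the knockout does without injury, the ganglia of both genotypes differed in few genes, among them genes of brown fat. Ucp1 (chromosome 8, 83290352 to 83298452) stood at 65.8 ± 20.1 CPM in the knockout against 0.642 ± 0.537 CPM in wild type (6.62 ± 0.60). Pck1, an enzyme of gluconeogenesis and of fat cells, stood at 17.9 ± 4.35 against 0.697 ± 0.422 CPM (4.71 ± 0.64), and Cidea, a lipid droplet protein, at 25.6 ± 7.33 against 3.75 ± 2.01 CPM (2.76 ± 0.44). The collagen gene Col1a1 was lower at 100.9 ± 34.4 against 361 ± 222 CPM (-1.84 ± 0.34).

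Elovl3, an elongase of brown fat, had 286 counts against 3, a ratio of 115 (counting interval 38.9 to 561). Etnppl (4.45 ± 0.49), the fatty acid transporter Cd36 (2.01 ± 0.37), the mast cell protease Prss34 (1.73 ± 0.31) and the ceramidase Acer2 (1.51 ± 0.24) were higher too, and Supt16, a histone chaperone, was lower (-1.11 ± 0.20). Interferon genes did not pass: Gbp2 stood at 34.1 ± 6.6 against 26.1 ± 4.88 CPM, Ifit3 at 61.8 ± 3.94 against 54.2 ± 3.59 CPM and B2m at 719 ± 69.4 against 506 ± 127 CPM. No list had a called member except endothelial and fibroblast markers, with Col1a1. As lists, IFNγ response (median 0.31; 2 higher and 1 lower over the list alone), type I interferon (0.29), class I (0.12), chemokines (0.11, 3 higher), cGAS-STING (0.34), regeneration (0.06, 4 higher), immediate early (0.33), macrophage (0.46), T and NK cell (0.34), neutrophil (0.80, 3 higher), red blood cell (0.85, 1 higher), satellite glia (0.43, 3 higher) and proliferation genes (0.83) were shifted up, and sensory neuron genes (-0.34) down. With an estimated correlation none of these 14 kept its call: camera adjusted p was 0.483, 0.5, 0.5, 0.483, 0.321, 0.5, 0.356, 0.483, 0.483, 0.321, 0.321, 0.321, 0.355 and 0.483 in this order. Class II, JAK-STAT, integrated stress response, endothelial and fibroblast, and Schwann cell lists did not pass (camera adjusted p = 0.0516, 0.846, 0.517, 0.0518 and 0.218), with 3 endothelial and fibroblast genes lower and 1 Schwann cell gene higher and 2 lower over the list alone. For endothelial and fibroblast markers the median was 0.18 while mean (-0.34) and test pointed down, and for JAK-STAT the median (0.04) and mean (-0.02) also differ in sign.

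edgeR's test called 25 of 18517 genes in sham ganglia, 20 higher and 5 lower, with 1607 genes at an unadjusted p below 0.05. The count depended on single libraries: 974 without wild-type sham replicate 2, 4 without replicate 3, and 60, 2 or 2 without knockout sham replicate 1, 2 or 3. Without wild-type sham replicate 1 it stayed at 25, with 10 higher and 15 lower. DESeq2 called 248 and limma-voom 3021 genes.

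With injury, the genotypes differed most in interferon genes, which is the comparison closest to the question of what Ptpn2 loss adds to an axon injury. Igtp (chromosome 11, 58199556 to 58207591) stood at 424 ± 55.7 CPM in injured knockout ganglia against 44.6 ± 4.77 CPM in injured wild type (3.25 ± 0.15), and Gbp2 at 714 ± 127 against 33.3 ± 1.39 CPM (4.42 ± 0.24). Saa3, an acute phase protein (chromosome 7, 46711998 to 46715700), stood at 93.5 ± 36 against 0.719 ± 0.012 CPM (7.01 ± 0.30). The myelin gene Pmp22 was lower in the knockout, at 3635 ± 519 against 7699 ± 1056 CPM (-1.08 ± 0.15).

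The largest differences also held the chemokines Cxcl9 (6.45 ± 0.62) and Ccl5 (79.2 ± 62.2 against 2.52 ± 0.683 CPM; 4.97 ± 0.62), Cplx3 (6.11 ± 0.66), Ly6i (5.38 ± 0.80), Gbp11 (5.26 ± 0.72) and Gbp10 (4.74 ± 0.55). Sct, the hormone secretin, was higher at a level of 5.84 ± 8.44 CPM that varied between libraries (6.07 ± 1.15). Lower in the knockout were Mobp (7.38 ± 2.9 against 44.9 ± 19.4 CPM; -2.60 ± 0.64), a myelin protein, Ifi202b (-2.59 ± 0.62), Prdm12 (-2.16 ± 0.53), a transcription factor of pain-sensing neurons, Plk5 (-1.99 ± 0.22), Emid1 (-1.97 ± 0.30), Lctl (-1.79 ± 0.23), Col26a1 (-1.70 ± 0.42) and Ddn (-1.63 ± 0.31).

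Of 28 IFNγ response genes 25 were higher in the injured knockout, also 25 when adjusted over the list alone, with a median of 3.00 (camera adjusted p = 1.04e-172; adjusted p = 3.76e-05 with an estimated correlation). These included Iigp1 (290 ± 36.2 against 16.3 ± 3.8 CPM) and Irgm1 (3.58 ± 0.21). Of 28 type I interferon-stimulated genes 24 were higher, 27 over the list alone (median 2.54, adjusted p = 0.00409 with an estimated correlation). Examples were Ifit3 (3.98 ± 0.30), Ifit1 (4.16 ± 0.43), Rtp4 (2.47 ± 0.23) and Zbp1 (3.87 ± 0.42). All 14 class I genes were higher, also over the list alone (median 1.68, adjusted p = 0.00104 with an estimated correlation), with Tap1 at 2.49 ± 0.25, Psmb8 at 2.73 ± 0.28, Psmb10 at 1.66 ± 0.16 and Psme2 at 1.59 ± 0.15. Of 18 chemokines and cytokines 6 were higher, 7 over the list alone, among them Ccl2 (2.40 ± 0.31), Ccl7 (2.21 ± 0.36) and Ccl12 (1.82 ± 0.29) (median 0.91, adjusted p = 0.0843 with an estimated correlation). Sting1 (1.51 ± 0.20) and Samhd1 (1.55 ± 0.24) were higher among 9 cGAS-STING genes, 3 over the list alone (median 0.05, adjusted p = 0.0843 with an estimated correlation). Among 19 JAK-STAT components Stat2 (1.44 ± 0.30) was higher, 2 over the list alone (camera adjusted p = 0.057). No class II gene passed, also 0 over the list alone (median 0.69, adjusted p = 0.355 with an estimated correlation).

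Of 28 regeneration-associated genes Arg1, an arginase of macrophages and injured neurons (29.7 ± 6.94 against 2.29 ± 0.66 CPM; 3.69 ± 0.45), and Sox11 (159 ± 26.9 against 69.5 ± 24.1 CPM; 1.19 ± 0.27), a transcription factor of growing neurons, were higher, 6 over the list alone (median 0.44, adjusted p = 0.0843 with an estimated correlation). Ddit3 was higher (1.06 ± 0.19) as 1 of 14 genes of the integrated stress response, also 1 over the list alone (camera adjusted p = 0.151). Among 18 macrophage and microglia markers Aif1 (1.82 ± 0.42) and Ctss (1.82 ± 0.44) were higher, 4 over the list alone (median 0.43, adjusted p = 0.566 with an estimated correlation), and among 10 T and NK cell markers Gzmb (3.72 ± 0.78), 3 over the list alone (median 1.03, adjusted p = 0.158 with an estimated correlation). Of 10 Schwann cell markers 4 were lower in the injured knockout, 8 over the list alone (median -0.85, adjusted p = 0.0148 with an estimated correlation): Pmp22, Pllp (-1.21 ± 0.15), Mal (-0.77 ± 0.14) and Mbp (5423 ± 719 against 11460 ± 94.5 CPM). Of 11 endothelial and fibroblast markers 3 were lower, 5 over the list alone (median -0.32, adjusted p = 0.158 with an estimated correlation): Col1a1 (-1.62 ± 0.34), Col1a2 (-1.05 ± 0.25) and Lum (-0.79 ± 0.17). Red blood cell genes were shifted down as a list without a called member (median -0.94, adjusted p = 0.355 with an estimated correlation). Sensory neuron genes (camera adjusted p = 0.216), satellite glia (0.468; 2 higher and 1 lower over the list alone), neutrophil (0.388), immediate early (0.509) and proliferation genes (0.464) did not pass and had no called member.

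edgeR's test called 407 of 18517 genes between the genotypes after injury, 257 higher and 150 lower, with 2448 genes at an unadjusted p below 0.05. Without wild-type injured replicate 1, 2 or 3 the count was 208, 199 or 197, and without knockout injured replicate 1 or 2 it was 194 or 235; 1877 genes passed when only both groups compared were fitted. The injured wild-type libraries are also part of the comparisons of injury in wild type and of RU521, so the errors of these comparisons are shared.

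**Figure D2:**
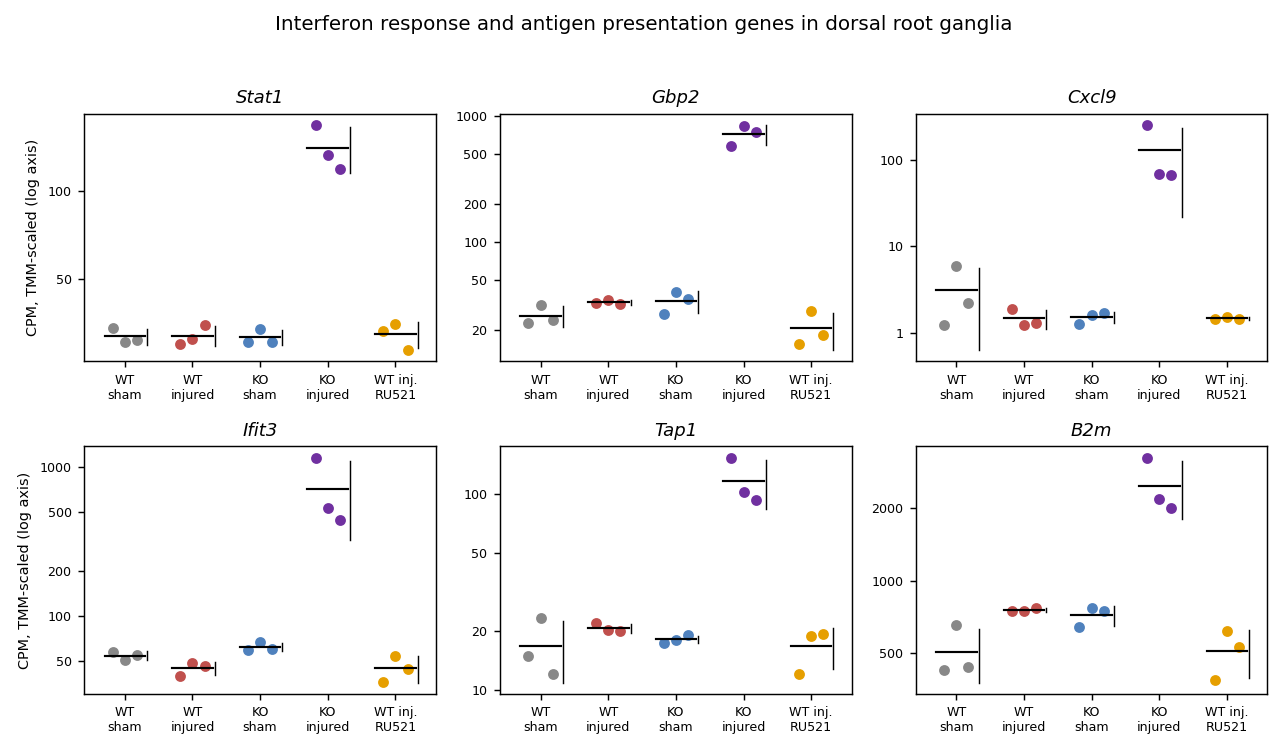
Levels of 6 interferon response and antigen presentation genes in ganglia (y axis, TMM-scaled CPM, log scale) for the 5 groups; points are libraries, lines means and bars SD (n = 3). Injured knockout libraries stand above all others, with Gbp2 at 714 CPM against group means of 20.8 to 34.1 CPM elsewhere.

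The interaction asks whether injury changed a gene by a different amount in the knockout than in wild type. Cxcl9 had the largest difference of log2 fold changes (7.45 ± 0.84), followed by Cplx3 (6.78 ± 1.37, a fitted value that rests on 3 counts in the sham knockout), Gbp11 (6.54 ± 0.98) and Saa3 (5.45 ± 0.48). Gbp2 (4.04 ± 0.31), Ifit3 (3.79 ± 0.38) and Arg1 (3.66 ± 0.65) rose more with injury in the knockout. Pck1 (-4.32 ± 0.89), Prss34 (-2.30 ± 0.43) and Plk5 (-2.29 ± 0.30) had lower fold changes in the knockout, for Pck1 from the high sham knockout level given above.

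Of 28 IFNγ response genes 16 had a higher injury fold change in the knockout, 25 over the list alone (median 2.57; camera adjusted p = 2.58e-111; adjusted p = 0.000201 with an estimated correlation), with Igtp at 2.75 ± 0.20, Iigp1 at 3.70 ± 0.31 and Gbp7 at 2.57 ± 0.23. Of 28 type I interferon-stimulated genes 11 did, 24 over the list alone (median 2.20, adjusted p = 0.0178 with an estimated correlation). Examples were Ifit1 (3.89 ± 0.56), Rtp4 (2.52 ± 0.32) and the virus-tethering protein Bst2 (3.14 ± 0.50). Of 14 class I genes 9 did, 14 over the list alone (median 1.55, adjusted p = 0.00688 with an estimated correlation). These included Tap1 (2.37 ± 0.34), Psmb10 (1.53 ± 0.22), Psme2 (1.48 ± 0.21) and Tapbp (1.33 ± 0.21). Of 18 chemokines and cytokines Ccl7 (2.59 ± 0.51) and Ccl2 (2.13 ± 0.44) did, 6 higher and 1 lower over the list alone (median 0.68, adjusted p = 0.403 with an estimated correlation). In the regeneration list Arg1 alone passed, also 1 over the list alone (median 0.29, adjusted p = 0.394 with an estimated correlation). Without called members, red blood cell (median -1.79; 4 lower over the list alone), Schwann cell (-0.74; 3 lower), proliferation (-0.996), neutrophil (-0.94), immediate early (-0.49) and endothelial and fibroblast lists (-0.40) were shifted down by camera, with adjusted p = 0.0964, 0.0912, 0.394, 0.349, 0.394 and 0.463 with an estimated correlation. Macrophage (camera adjusted p = 0.643), cGAS-STING (0.45), JAK-STAT (0.087), T and NK cell (0.0902), satellite glia (0.0565), sensory neuron (0.175), class II (0.301) and integrated stress response genes (0.42) did not pass; for macrophage markers the median was 0.04 while the test pointed down.

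edgeR's test called 83 of 18517 genes for the interaction, 57 higher and 26 lower, with 1811 at an unadjusted p below 0.05. Without wild-type sham replicate 2 it called 666 (255 higher, 411 lower) and without wild-type sham replicate 3 it called 52. Without wild-type injured replicate 1, 2 or 3 it called 46, 38 or 39, without knockout sham replicate 2 or 3 it called 41 or 37, and without knockout injured replicate 1 it called 52. The share of higher calls fell from 68.7% to 38.1% when both libraries that stood apart from their groups (wild-type sham replicate 2 and RU521 replicate 1) were left out.

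**Figure D3:**
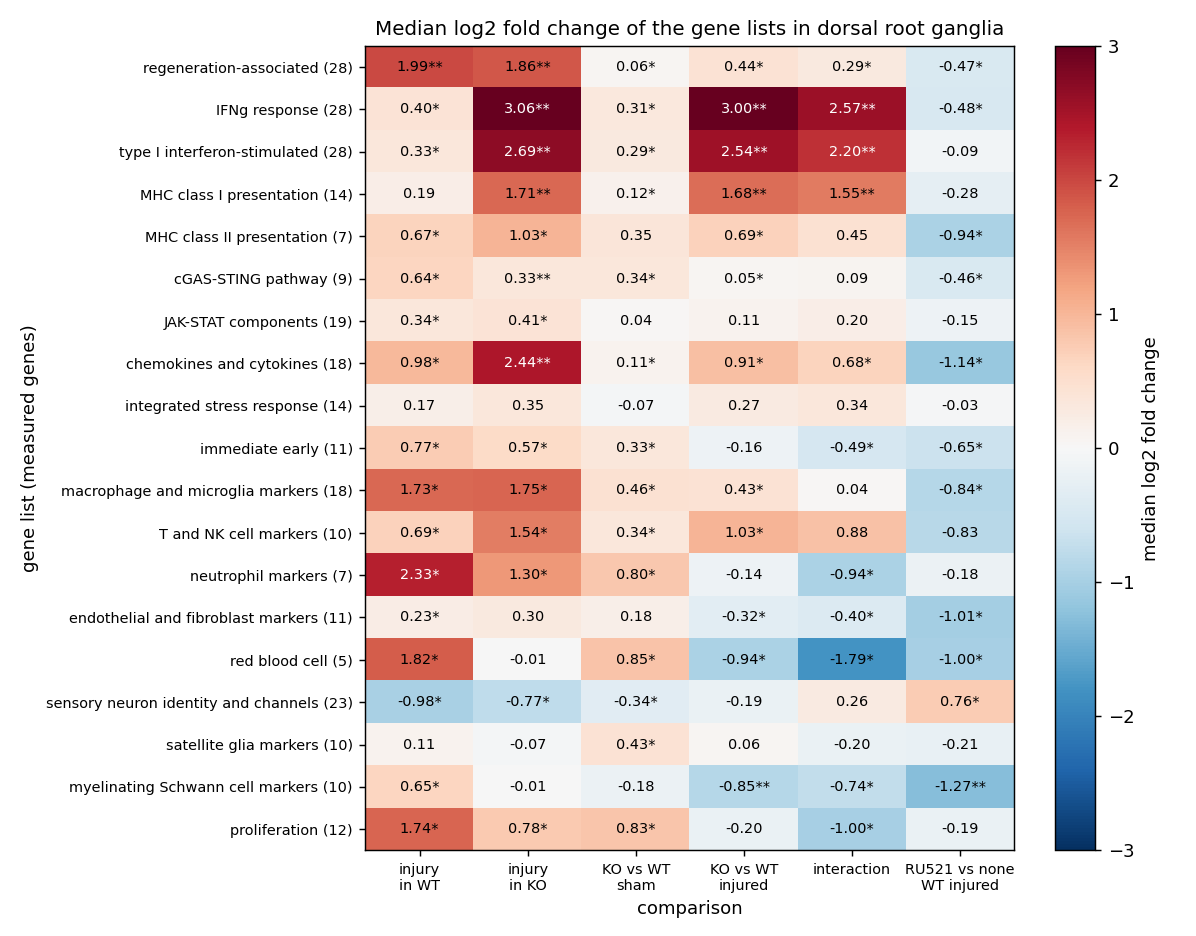
Median log2 fold change of the 19 gene lists (rows; number of measured genes in brackets) in the 6 ganglion comparisons (columns); one star marks a camera call and a second star a call that holds with an estimated correlation. The IFNγ response list had medians of 3.06 for injury in the knockout and 3.00 for knockout against wild type after injury, and 0.40 for injury in wild type.

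RU521 asks what the cGAS pathway adds to the injury response of wild-type ganglia. Whether the other injured mice received a vehicle is not given in the sources used here, so drug and injection are not separated. Cgas, which encodes the target of RU521, stood at 1.17 ± 0.716 CPM with RU521 against 2.15 ± 0.525 CPM without and did not pass (-0.88 ± 0.47); since RU521 inhibits the protein, the transcript does not check the treatment. The peptide genes Cartpt (64.1 ± 3.32 against 13.6 ± 3.21 CPM; 2.23 ± 0.23) and Uts2b (31.7 ± 14.4 against 2.08 ± 1.31 CPM; 3.94 ± 0.52) rose. Cebpd, a transcription factor of inflammation, fell from 40.2 ± 3.3 to 3.11 ± 0.302 CPM (-3.69 ± 0.64), and C1qc, a complement subunit of macrophages, from 99.8 ± 14.7 to 12.8 ± 5.42 CPM (-2.96 ± 0.44).

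Other large increases with RU521 were in Lypd1 (3.46 ± 0.60), the vesicle calcium sensor Syt7 (2.37 ± 0.34), the transcription factor Pou4f2 (2.32 ± 0.40), Ajm1 (2.27 ± 0.40), the potassium channel Kcnd3 (2.10 ± 0.30) and Wipf3 (2.03 ± 0.34). Large decreases were in P3h2 (-3.53 ± 0.61), which modifies collagen, the matrix protein Fmod (-2.67 ± 0.57), Cox11 (-2.66 ± 0.64), Ccdc3 (-2.64 ± 0.53), Bloc1s4 (-2.63 ± 0.62) and the Notch target Hes1 (-2.62 ± 0.56). Of 23 sensory neuron genes 12 rose, 14 over the list alone (median 0.76, adjusted p = 0.214 with an estimated correlation). These included Calca (2352 ± 164 against 1020 ± 212 CPM), Tac1 (1.74 ± 0.26) and the sodium channels Scn9a (1.37 ± 0.23) and Scn10a (1.79 ± 0.33). All 10 Schwann cell markers fell, also over the list alone (median -1.27; camera adjusted p = 1.18e-18; adjusted p = 0.013 with an estimated correlation), with Pmp22 at 3043 ± 53.8 against 7699 ± 1056 CPM, Mag at -1.39 ± 0.15, Pllp at -1.26 ± 0.15 and Mal at -1.02 ± 0.14. Of 11 endothelial and fibroblast markers 7 fell, 10 over the list alone (median -1.01, adjusted p = 0.13 with an estimated correlation). Examples were Lum (-1.25 ± 0.17), Dcn (-1.17 ± 0.22), Pdgfra (-1.32 ± 0.26) and the tight junction gene Cldn5 (-0.74 ± 0.15). Of 18 macrophage and microglia markers 4 fell, 8 over the list alone (median -0.84, adjusted p = 0.259 with an estimated correlation): C1qc, Cx3cr1 (-1.52 ± 0.34), Adgre1 (-1.37 ± 0.36) and Mrc1 (-1.33 ± 0.32). Markers of these cell types were thus lower and neuronal genes higher with RU521, so effects within a cell type cannot be separated here from a change of composition.

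Of 28 regeneration-associated genes 7 fell with RU521, 1 higher and 11 lower over the list alone (median -0.47, adjusted p = 0.259 with an estimated correlation). Among them were Gal (173 ± 75.6 against 396 ± 118 CPM; -1.20 ± 0.28), Gadd45a (-1.52 ± 0.30) and the tubulin Tubb6 (-1.11 ± 0.24). Of 28 IFNγ response genes 3 fell, 7 over the list alone: Gbp9 (-1.14 ± 0.22), Tgtp1 (-1.67 ± 0.34) and Serping1 (-0.63 ± 0.16) (median -0.48, adjusted p = 0.259 with an estimated correlation). Type I interferon-stimulated genes did not pass in any member, also 0 over the list alone, or as a list (median -0.09; camera adjusted p = 0.438), and Ifit3 stood at 44.7 ± 8.93 against 44.7 ± 4.66 CPM. Of 18 chemokines and cytokines 5 fell, 8 over the list alone, such as Csf1 (-1.33 ± 0.31), Ccl12 (-1.31 ± 0.30), Cx3cl1 (-1.25 ± 0.34) and Il33 (-1.17 ± 0.33) (median -1.14, adjusted p = 0.259 with an estimated correlation). Of 11 immediate early genes 4 fell, 5 over the list alone: Egr2 (-1.53 ± 0.40), Egr1 (-0.99 ± 0.19), Fos (-0.96 ± 0.27) and Nr4a1 (-0.54 ± 0.16) (median -0.65, adjusted p = 0.214 with an estimated correlation). Of 7 class II genes 2 fell, 3 over the list alone, H2-DMb1 (-1.44 ± 0.28) and H2-DMa (-0.81 ± 0.17) (adjusted p = 0.259 with an estimated correlation).

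Of 9 cGAS-STING genes 1 fell, also 1 over the list alone, Rela (-0.58 ± 0.17), a subunit of NF-kB (median -0.46, adjusted p = 0.259 with an estimated correlation). Red blood cell genes were shifted down with 0 called, 1 lower over the list alone (median -0.997, adjusted p = 0.405 with an estimated correlation). JAK-STAT components (1 lower, the receptor chain Ifnar2 at -0.55 ± 0.16; camera adjusted p = 0.331) and satellite glia (1 lower, 2 over the list alone; 0.158) did not pass as lists. Class I (0.186), T and NK cell (0.0918), neutrophil (0.428), proliferation (0.428) and integrated stress response genes (0.953) had no called member and did not pass either.

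edgeR's test called 1774 of 18517 genes with RU521, 944 higher and 830 lower. RU521 replicate 1 stood apart in the first principal component, with 28803 detected genes and 7.83% mitochondrial counts, and without it 691 genes were called (240 higher, 451 lower). Without RU521 replicate 2 or 3 the count was 2727 or 828, and without injured wild-type replicate 1, 2 or 3 it was 1117, 476 (195 higher, 281 lower) or 590 (242, 348). With only the groups compared in the fit, 798 were higher and 975 lower, so the main direction is not settled. The 1174 genes raised by injury in the knockout had a median change of -0.38 (quartiles -0.75 and -0.08) with RU521, 939 of them negative and 145 called lower (camera p = 1.76e-13; p = 0.133 with an estimated correlation). The 847 genes lowered by injury in the knockout had a median of 0.50 (quartiles 0.14 and 0.88), with 244 called higher (camera p = 4.05e-26; p = 0.0569 with an estimated correlation).

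**Figure D4:**
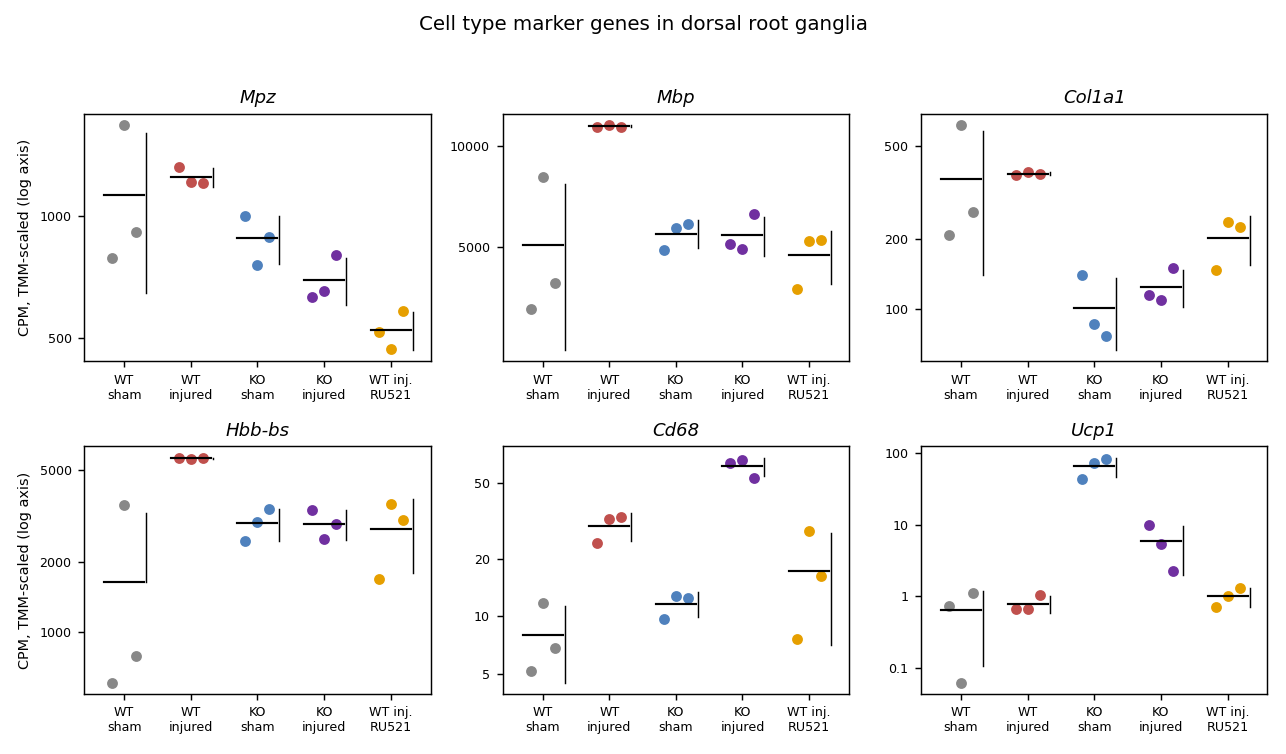
Levels of cell type marker genes in ganglia (y axis, TMM-scaled CPM, log scale) for the 5 groups; points are libraries, lines means and bars SD (n = 3). Mbp stood at 11460 CPM in injured wild type and between 4715 and 5475 CPM as the group means elsewhere, and Ucp1 at 65.8 CPM in the sham knockout.

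In retinal ganglion cells, IFNγ given to wild-type eyes went with higher class I and type I interferon-stimulated genes as lists, but no single gene passed the test. Oasl2, an interferon-induced protein (chromosome 5, 114896936 to 114912234), stood at 69.3 ± 55 CPM with IFNγ and had 0 counts with PBS, at least 304-fold by the counting floor. Psmb9, a subunit of the immunoproteasome, stood at 8.17 ± 3.83 CPM against 0, at least 35.8-fold, and B2m at 2124 ± 1176 against 224 ± 192 CPM (3.24 ± 0.64). H2-K1, a class I heavy chain, stood at 1717 ± 1153 against 133 ± 68.8 CPM (3.69 ± 0.68). The comparison asks what IFNγ does to retinal ganglion cells of wild-type eyes after injury. Fitted folds of genes with 0 counts in a group depend on the prior count of edgeR, so bounds are given for them.

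As a list, 21 type I interferon-stimulated genes were shifted up by IFNγ in wild type, 20 of them positive and 6 higher over the list alone (median 7.14, or 4.06 with genes at their bound; camera adjusted p = 4.98e-20; adjusted p = 0.0333 with an estimated correlation). They included Ifit1 (at least 161-fold), Rtp4 (at least 73.9-fold) and Ifi44 (at least 57.1-fold). The 14 class I genes were shifted up as well, 11 of them positive and 7 higher over the list alone (median 2.27, adjusted p = 0.031 with an estimated correlation), with H2-D1 at 2269 ± 1163 against 497 ± 353 CPM. Of 18 IFNγ response genes 13 were positive and 8 higher over the list alone (median 3.31, or 2.86 with bounds; camera adjusted p = 6.67e-09; adjusted p = 0.269 with an estimated correlation). Among them were Gbp7 (at least 32-fold) and Irf1 (at least 9.3-fold). Müller glia and astrocyte markers were shifted up (8 measured; median 1.47, adjusted p = 0.269 with an estimated correlation), and Clu, a secreted chaperone of glia, stood at 2912 ± 1457 against 808 ± 220 CPM. None of these genes was called over all genes.

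Genes of retinal ganglion cell identity (17 measured; median 0.24; camera adjusted p = 0.168) and of regeneration (27; 0.22; 0.168) did not pass in wild type, with the synuclein Sncg at 2216 ± 522 against 1720 ± 1113 CPM and the growth cone protein Gap43 at 2595 ± 1299 against 2150 ± 715 CPM. Rod photoreceptor markers (8; median -4.62, or -4.14 with bounds; 0.168), macrophage markers (5; 7.18, or 2.54 with bounds; 0.0664), neuronal apoptosis (13; 0.37; 0.588), chemokines (6; 1.04; 0.213), immediate early (10; 0.55; 0.39), integrated stress response (15; -0.14; 0.39), JAK-STAT (16; 0.04; 0.911) and cGAS-STING genes (5; -0.13; 0.823) did not pass either. For JAK-STAT the median was positive and the test pointed down. Lists with fewer than 5 measured genes were only counted and had no called member: class II (4), amacrine and horizontal cell (2), and 1 each for T and NK cell, neutrophil, red blood cell, cone and bipolar cell markers; of endothelial and fibroblast markers none was measured. edgeR's test called 0 of 13487 genes, with 542 at an unadjusted p below 0.05; DESeq2 called 239 and limma-voom 0. Without wild-type IFNγ replicate 1, edgeR called 1 gene.

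IFNγ in Ptpn2 knockout eyes, asked as the same question in the knockout, changed no gene past the threshold. Heg1, a receptor of vessel and heart development, stood at 26.7 ± 12.4 CPM with IFNγ and had 0 counts with PBS, at least 155-fold. Cdr1os stood at 94.2 ± 58.4 against 0.858 ± 0.793 CPM (6.77 ± 1.08) and Proser1 at 44.4 ± 44.1 against 0.476 ± 0.394 CPM (6.52 ± 1.19). Igtp, high in the knockout already without IFNγ, stood at 177 ± 39.6 against 198 ± 158 CPM.

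By camera, type I interferon-stimulated genes (19 of 21 positive; median 1.92, adjusted p = 0.292 with an estimated correlation), retinal ganglion cell identity (13 of 17; 1.03; 0.212) and regeneration genes (20 of 27; 0.86; 0.292) were shifted up by IFNγ in the knockout, none with a member higher over the list alone. Stmn2, a tubulin-binding protein of neurons, stood at 1628 ± 1415 against 502 ± 209 CPM and Gap43 at 1562 ± 742 against 815 ± 372 CPM. Macrophage markers (0 of 5 positive, 1 lower over the list alone; median -6.63, adjusted p = 0.292 with an estimated correlation) and cGAS-STING genes (0 of 5, 1 lower over the list alone; -1.64; 0.212) were shifted down; Ctss stood at 498 ± 862 CPM in the PBS group, all of it from replicate 2. IFNγ response genes (median 0.09; camera adjusted p = 0.316), class I (0.43; 0.137) and the other lists (0.0591 or higher) did not pass. edgeR's test called 0 of 13487 genes, with 879 at an unadjusted p below 0.05; DESeq2 called 409 and limma-voom 1. Without knockout PBS replicate 2 or 3, edgeR called 3 or 1.

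Without IFNγ, class I antigen presentation genes were shifted up in knockout retinal cells against wild type, the comparison of what Ptpn2 loss does by itself. Oasl2 stood at 117 ± 141 CPM against 0 counts (at least 515-fold) and Psmb9 (chromosome 17, 34181987 to 34187764) at 29.3 ± 15.7 CPM against 0 (at least 128-fold); both were called. Heg1 was called lower, with 0 counts against 45.3 ± 27.8 CPM (at least 263-fold).

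All 14 class I genes were positive, 1 called and 10 higher over the list alone (median 2.28; camera adjusted p = 1.24e-18; adjusted p = 0.0432 with an estimated correlation). All 18 IFNγ response genes were positive, 0 called and 12 higher over the list alone (median 9.51, or 5.61 with genes at their bound, adjusted p = 0.114 with an estimated correlation). Among them were Irgm2 (at least 186-fold), Gbp6 (at least 162-fold), Gbp2 (at least 135-fold) and Igtp (198 ± 158 against 3.32 ± 5.69 CPM). Of 21 type I interferon-stimulated genes 19 were positive, 1 called and 5 higher over the list alone (median 5.49, or 4.98 with bounds, adjusted p = 0.118 with an estimated correlation). Examples were Ifit1 (at least 231-fold) and Oas1a (at least 171-fold). Immediate early genes (10 of 10 positive, 1 higher over the list alone; median 1.14, adjusted p = 0.184 with an estimated correlation), Müller glia markers (8 of 8; 2.47; 0.158) and neuronal apoptosis genes (11 of 13; 0.87; 0.118) were shifted up. Ctss and Ccl12, a chemokine, had 0 counts in wild type with PBS and stood at 1493 and 280 CPM in knockout PBS replicate 2 and at 0 in replicates 1 and 3. The macrophage list did not pass (median 11.61, or 7.60 with bounds, 4 of 5 higher over the list alone; camera adjusted p = 0.144). Regeneration genes did not pass (median -0.27, mean 0.79 and the test down, 1 lower over the list alone; camera adjusted p = 0.353), with Stmn2 at 502 ± 209 against 1738 ± 370 CPM, and neither did identity genes (-0.32; 0.144) or the remaining lists (0.127 or higher). For rod markers the median (-0.48) and mean (-0.61) were negative while the test pointed up.

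Knockout PBS replicates 1 and 2 stood apart from the other retinal libraries and from each other, at -174 and 160.6 on the first principal component. edgeR's test called 3 of 13487 genes for the knockout with PBS, with 1281 at an unadjusted p below 0.05; DESeq2 called 653 and limma-voom 4. Without wild-type PBS replicate 1, 2 or 3 edgeR called 0, 2 or 8 genes, and without knockout PBS replicate 2 or 3 it called 6 or 11.

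With IFNγ in both genotypes, the comparison that asks whether Ptpn2 loss adds to IFNγ, no gene passed. Igtp stood at 177 ± 39.6 CPM in the knockout against 7.91 ± 10.5 CPM in wild type (4.48 ± 1.75). The smallest p-values belonged to Nup43, a nuclear pore protein (0 counts against 12.4 ± 8.37 CPM, at least 59.9-fold lower), Maged1 (640 ± 150 against 2041 ± 758 CPM; -1.67 ± 0.36) and the phosphatase Dusp5 (2 counts against 1216; ratio 0.00166, counting interval 0.000201 to 0.00601).

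By camera, IFNγ response genes (18 of 18 positive; median 3.32, adjusted p = 0.324 with an estimated correlation), class I genes (12 of 14; 1.41; 0.348) and type I interferon-stimulated genes (21 of 21; 1.77; 0.452) were shifted up in the knockout with IFNγ, and macrophage markers (0 of 5; -2.07; 0.348) and the integrated stress response (5 of 15; -0.56; 0.501) down, all with 0 members over the list alone. B2m stood at 3857 ± 1880 against 2124 ± 1176 CPM and the interferon gene Ifit2 at 673 ± 749 against 56.4 ± 23.7 CPM. The other lists did not pass (camera adjusted p = 0.083 or higher). edgeR's test called 0 of 13487 genes, also without any single library, with 668 at an unadjusted p below 0.05; DESeq2 called 281 and limma-voom 5.

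The interaction in retinal cells asks whether IFNγ acted by a different amount in the knockout. No gene passed: Heg1 had adjusted p = 0.105, Rab7b 0.195 and Psmb9 0.249 by edgeR's test. Lists of IFNγ response (median -3.39; 1 lower over the list alone), type I interferon (-3.43; 3 lower) and class I genes (-1.73; 3 lower) had smaller IFNγ effects in the knockout by camera, as did chemokines (-2.56), macrophage (-13.13; 4 lower) and Müller glia markers (-2.30). The macrophage value rests on knockout PBS replicate 2, with Ctss at 1493 CPM there and 0 in replicates 1 and 3. With an estimated correlation these 6 lists gave camera adjusted p = 0.297, 0.22, 0.22, 0.22, 0.22 and 0.22. Genes with 0 counts in a group give fitted values here that depend on the prior count. The other lists did not pass (camera adjusted p = 0.0561 or higher). edgeR's test called 0 of 13487 genes, also without any single library, with 721 at an unadjusted p below 0.05; DESeq2 called 380 and limma-voom 1.

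Knockout cells with IFNγ were compared with wild-type cells with PBS to ask what both together do, and antigen presentation genes rose. B2m (chromosome 2, 122147686 to 122153083) rose from 224 ± 192 to 3857 ± 1880 CPM (4.10 ± 0.66) and Tap1 from 0.305 ± 0.448 to 55.2 ± 13 CPM (7.40 ± 1.19). Oasl2 (222 ± 96.5 CPM, at least 975-fold), Gbp6 (68.9 ± 51.1 CPM, at least 302-fold) and Psmb9 (36 ± 19 CPM, at least 158-fold) were called against 0 counts. Camk2a, a neuronal kinase, rose from 14.1 ± 10 to 408 ± 189 CPM (4.86 ± 0.76), and the ribosomal gene Rpl5 fell from 634 ± 35.8 to 164 ± 10.4 CPM (-1.95 ± 0.31).

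All 18 IFNγ response genes were positive, 1 called and 12 higher over the list alone (median 9.88, or 5.77 with genes at their bound; camera adjusted p = 1.19e-24; adjusted p = 0.0288 with an estimated correlation). Examples were Gbp7 (at least 180-fold), Gbp2 (at least 128-fold) and Irgm2 (at least 114-fold). All 21 type I interferon-stimulated genes were positive, 1 called and 17 higher over the list alone (median 9.54, or 6.40 with bounds, adjusted p = 0.0271 with an estimated correlation). Among them were Ifit1 (at least 878-fold), Rtp4 (at least 188-fold) and Rsad2 (at least 185-fold). All 14 class I genes were positive, 3 called and 10 higher over the list alone (median 3.48, adjusted p = 0.019 with an estimated correlation). Genes of the integrated stress response were shifted down (3 of 15 positive; median -0.69, adjusted p = 0.3 with an estimated correlation), with Ddit3 at 924 ± 809 against 2250 ± 991 CPM, and Müller glia markers up (8 of 8; 1.75, or 1.60 with bounds; 0.277). Identity genes (0.19; camera adjusted p = 0.159), regeneration genes (0.37; 0.159) and the other lists (0.0893 or higher) did not pass; for macrophage markers the median was 5.11, or 0.40 with bounds, while the test pointed down (0.765). Sncg stood at 2829 ± 998 against 1720 ± 1113 CPM and Gap43 at 1562 ± 742 against 2150 ± 715 CPM.

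edgeR's test called 7 of 13487 genes for both together, 6 higher and 1 lower, with 1058 at an unadjusted p below 0.05; DESeq2 called 434 and limma-voom 23. Without wild-type PBS replicate 1, 2 or 3 edgeR called 0, 2 or 0 genes, and without knockout IFNγ replicate 1 or 2 it called 0 or 3. Retinal libraries varied: between 8.19% and 22.4% of the genes at 10 CPM or more in 1 library of a group had 0 counts in another of the same group, the highest share in the knockout with PBS. In simulated data, edgeR found 20.8% of genes changed by a log2 of 4 and 1.52% of those changed by 2, with 0 false calls. Of DESeq2's calls 79.3% were false.

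**Figure D5:**
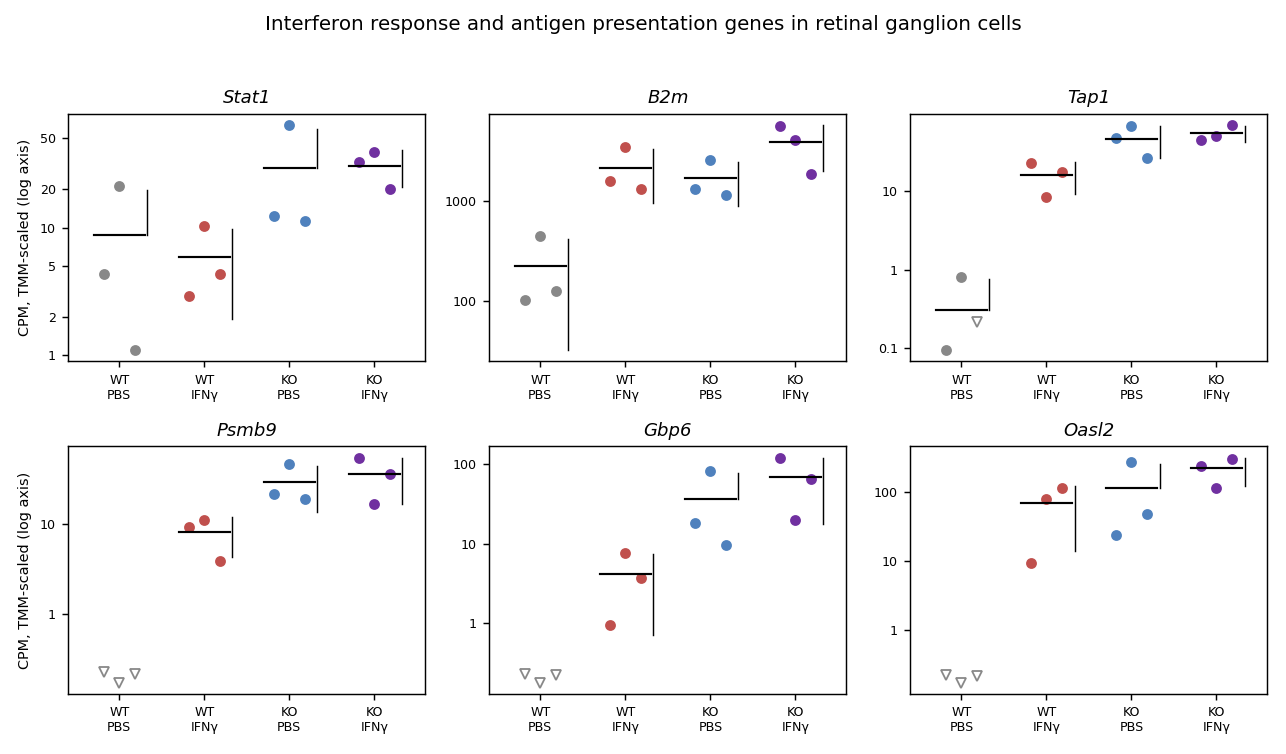
Levels of 6 interferon response and antigen presentation genes in retinal ganglion cells (y axis, TMM-scaled CPM, log scale) for the 4 groups; points are libraries, open triangles mark libraries with 0 counts at their floor, lines are means and bars SD (n = 3). B2m stood at 224 CPM in wild type with PBS, 2124 CPM in wild type with IFNγ, 1681 CPM in the knockout with PBS and 3857 CPM in the knockout with IFNγ.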

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

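The tests of this part were chosen after the results were seen, except those said below to be written before.

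All of the following were picked out because a test of the difference between 2 groups, the interaction, passed. In ganglia, 83 genes changed by a different amount with injury in the knockout than in wild type. Among the named genes the difference of log2 fold changes was 7.45 for Cxcl9, 6.78 for Cplx3, 6.54 for Gbp11, 5.45 for Saa3, 4.04 for Gbp2, 3.89 for Ifit1, 3.79 for Ifit3, 3.70 for Iigp1, 3.66 for Arg1, 3.14 for Bst2, 2.75 for Igtp, 2.59 for Ccl7, 2.57 for Gbp7, 2.52 for Rtp4, 2.37 for Tap1, 2.13 for Ccl2, 1.53 for Psmb10, 1.48 for Psme2 and 1.33 for Tapbp. It was -4.32 for Pck1 (from its high sham knockout level), -2.30 for Prss34 and -2.29 for Plk5. Lists picked out by the same test had medians of 2.57 (IFNγ response), 2.20 (type I interferon), 1.55 (class I), 0.68 (chemokines) and 0.29 (regeneration), and -0.49 (immediate early), -0.94 (neutrophil), -0.40 (endothelial and fibroblast), -1.79 (red blood cell), -0.74 (Schwann cell) and -0.996 (proliferation). With an estimated correlation the first 3 kept their call, and the other 8 lost it (camera adjusted p = 0.403, 0.394, 0.394, 0.349, 0.463, 0.0964, 0.0912 and 0.394 in this order). In retinal cells camera with its preset correlation picked out a smaller IFNγ effect in the knockout for IFNγ response (-3.39), type I interferon (-3.43), class I (-1.73), chemokine (-2.56), macrophage (-13.13) and Müller glia genes (-2.30). With an estimated correlation all 6 lost the call (adjusted p = 0.297 for IFNγ response and 0.22 for each of the others), so a difference between the genotypes is not established there, and the macrophage value rests on knockout PBS replicate 2.

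The first pattern is the rise of interferon genes in injured knockout ganglia. A rise only in proportion to immune cells is argued against by their 3 lists. The highest median was 1.03 (T and NK cells) against 3.00 (quartiles 1.68 and 3.76) for IFNγ response genes. Of all 28 measured IFNγ response genes, called or not, 25 had their lowest injured knockout library above all 12 other libraries, which argues against a single library as the cause. Which cells carry the transcripts, and whether immune cells induced them in others, stays open in bulk tissue.

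The second pattern is that Schwann cell genes were highest in injured wild-type ganglia without RU521. Injury as the cause stays open: their median change was -0.005 with injury in the knockout against 0.65 in wild type, but this is part of the pattern itself, and the interaction lost its call with an estimated correlation (camera adjusted p = 0.0912). An equal shift of all cells other than neurons is argued against by satellite glia, with a median of -0.21 with RU521 (quartiles -0.51 and 0.01) against -1.27 (-1.34 and -1.11) for Schwann cells, although endothelial and fibroblast (-1.01), red blood cell (-0.997) and macrophage genes (-0.84) were lower too. In a test written before its result, 10 of 10 Schwann cell genes were still called lower with RU521 with the number of detected genes as a covariate (median -0.96). A shift shared by Schwann cells, fibroblasts and macrophages, such as from a larger piece of nerve in the dissection of 1 group, stays open, since no table separates it from the group.

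The third pattern is the brown fat genes in sham knockout ganglia. Adipose tissue in the dissected ganglia was tested with a list written before its result: 20 of 24 measured adipocyte genes were higher, with a median of 1.35 (quartiles 0.35 and 2.11), which is in line with adipose tissue, while the 19 genes not called had a median of 0.73. An effect of the knockout that does not depend on injury stays open: between injured genotypes the same 24 genes had a median of -0.20 (quartiles -0.33 and 0.04), but the 5 called in sham had 1.09 (0.39 and 2.25; 4.71 in sham), and they were picked by their sham values. Adipose tissue stays open too. Of the 24 genes 19 reached 1 CPM in wild-type sham, which cannot decide it. Replicate 2 carried most of Fabp4, Car3, Cfd and Adipoq there and least of Ucp1 and Cidea.

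Other splits of the same libraries into groups of 3 were tested for their counts of calls. For 10 possible splits no share under 0.05 can be reached, so only the values are given: for injury in wild type 1 split reached the real 3070 calls (highest other 6), for injury in the knockout 1 reached 2021 (0), for genotype in injured ganglia 1 reached 407 (0) and for RU521 1 reached 1774 (0). For genotype in sham ganglia 2 of 10 reached 25, the real groups and a split that called 905. That split points to a structure of the samples: it sets wild-type sham 1 and 3 and knockout sham 1 against the other 3 libraries. For the ganglion interaction 5 of 100 drawn splits called at least the real 83 (highest other 171), so chance is not excluded. In retinal cells 10 of 10 splits reached the 0 calls for IFNγ in wild type (highest other 0), for IFNγ in the knockout (1) and for genotype with IFNγ (0). There 1 of 10 reached the 3 calls for genotype with PBS (1) and 1 of 10 the 7 calls for both together (2), while for the interaction 100 of 100 reached 0 (1).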

How the results depend on the processing

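The values of added alternatives (number of detected genes as a covariate, both apart libraries left out) were chosen after the results were seen; the others were fixed before the data were examined. No call turned direction under any alternative except S100a9 with RU521, 0.59 with the covariate against -0.05 in the test of the report (adjusted p = 0.0406); the cause was not tested. Counts of called genes moved, and unless said otherwise the cause was not tested. For injury in wild type (3070) they were 9264 with limma-voom, 1702 with only the groups compared, 847 with the covariate, 7313 with both apart libraries left out, and 1240 to 6513 without 1 library. For injury in the knockout (2021) they were 4417, 4102, 3114, 4556 and 869 to 1388 in the same order. For genotype in sham ganglia (25) they were 596 without the low count filter, 248 with DESeq2, 3021 with limma-voom, 2 with only the groups compared, 195 with the covariate, 1939 with both left out and 2 to 974 without 1 library. For genotype in injured ganglia (407) they were 711, 721, 2101, 1877, 1372, 1510 and 194 to 293 in this order. For the ganglion interaction (83) they were 423 without the filter, 260 with DESeq2, 2008 with limma-voom, 397 with the covariate, 1468 with both left out and 37 to 666 without 1 library; its share of higher calls, 68.7%, was 49.4% without the filter and 38.8% with limma-voom. For RU521 (1774) they were 2767 with DESeq2, 6175 with limma-voom and 476 to 2727 without 1 library.

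In retinal cells, without the filter, with DESeq2 and with limma-voom, the counts were 2, 239 and 0 for IFNγ in wild type (0; 0 to 1 without 1 library) and 2, 409 and 1 for IFNγ in the knockout (0; 0 to 3). They were 23, 653 and 4 for genotype with PBS (3; 0 to 11) and 12, 434 and 23 for both together (7; 0 to 5), and with only the groups compared 0 for both of these. For genotype with IFNγ (0) DESeq2 called 281 and limma-voom 5; for the interaction (0) 4 passed without the filter, 380 with DESeq2 and 1 with limma-voom. In simulated data 79.3% of DESeq2's calls were false for both together in retinal cells, 23.8% for injury in wild-type ganglia and 16.4% for the ganglion interaction.

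The replicate number as a block moved the count to 71 for genotype in sham ganglia, 130 for the ganglion interaction, 0 for genotype with PBS and 1 for both together in retinal cells, and no other count by over 1.5 times. The numbers were not taken as pairs: correlations of same-numbered libraries ran from -0.116 to 0.267 in ganglia and from -0.0242 to 0.0557 in retinal cells, and 6 of 15 and 6 of 12 libraries correlated best with their own number. An estimated correlation removed 63 ganglion and 25 retinal camera calls (114 and 84 tests, called or not). Shared injury calls (1108) were 1111 with DESeq2 size factors, 1638 unfiltered and 1488 with the block. RU521 medians of injury genes kept their sign there (covariate and omitted libraries not tested). Of the called named genes, 37 of 74, 46 of 70, 1 of 9, 31 of 47, 16 of 23 and 30 of 50 kept their call in all alternatives in the 6 ganglion comparisons, and 0 of 3 and 0 of 7 in retinal cells. At this depth, retinal groups with 0 counts allow only a bound on the fold.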

Other observations

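The genes of this part were chosen after their values were seen. No list of them was tested, and other genes of their kinds were not counted. In injured ganglia, 6 genes of endoplasmic reticulum chaperones and their partners were higher in the knockout than in wild type: Hspa5 at 740 ± 53.4 against 406 ± 18.1 CPM (0.87 ± 0.13, n = 3), Sdf2l1 (1.30 ± 0.18), Creld2 (0.93), Manf (0.80), Pdia6 (0.69) and Calr (0.62), all with an edgeR adjusted p between 0.000493 and 0.00515. Also higher were the acute phase gene Saa1 (48.7 ± 13.2 against 6.03 CPM; 3.01 ± 0.36) and its relative Saa2 (4.04), the metallothioneins Mt1 (1.06) and Mt2 (1.83), Acod1 (3.44), an enzyme of activated macrophages, and Ubd (4.35), a ubiquitin-like modifier induced by interferon. None of them was called between the genotypes in sham ganglia. With RU521 Saa1 fell (-1.45) and Manf rose (0.55).

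Transcripts of Ifng and Ifnb1, the 2 interferon genes counted, were near or under the floor. Ifng had 5, 6, 1, 13 and 0 counts over the 3 libraries of wild-type sham, wild-type injured, knockout sham, knockout injured and RU521 ganglia, and Ifnb1 had 1, 6, 1, 2 and 4. Both had 0 counts in all retinal libraries.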
